A study of Homo sapiens with 4 samples.

How the data were processed

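Total RNA was purified from pellets of stably transfected SK-mel-28 cells, converted to biotinylated cRNA and hybridised, per the labels' protocols. The deposited tables hold 1 value for each of 22277 probe sets on 4 arrays. Values are intensity on a linear scale, and the authors made them with RMA, per the submitters' processing notes, which give no version. RMA corrects the background, normalises quantiles across arrays and summarises the probes of a probe set on the log2 scale, so the linear values are taken to be back-transformed, a step that the sources used here do not state. The array type and the annotation version are not given in the sources used here. Quantile normalisation makes the arrays' distributions alike, so a global rise or fall of RNA cannot be seen and differences are relative to the bulk of the genes. Differences of dim probe sets may also be compressed where background signal remains after the correction. The tables carry no detection calls.

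Of 2 deposited tables, the one with a column per sample was used, and the other held the same values within a relative difference of 4.98e-10. Log2 of the intensity was taken without a pseudocount, since the lowest value was 8.15. The 62 control probe sets were left out of all tests, leaving 22215. Gene symbols came from the description column of the second table: 20374 probe sets had 1 symbol, 583 had several and 1258 had none. Of the single symbols, 18567 were current in NCBI's RefSeq gene table for GRCh38.p14, 1531 were updated through a synonym held by 1 gene and 276 were kept as given. No gene was named from a probe set with several symbols. Each of 12748 genes was represented by its probe set of highest mean log2 value over the 4 arrays, and its other probe sets can disagree with that value. Probe sets were called in both directions for 61 genes. No coordinates are given, since the tables name no genome build.

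The 2 EWI-2 shRNA arrays were compared with the 2 control shRNA arrays with limma 3.58.1 in R 4.3.3, by lmFit and eBayes without covariates, leaving 2 residual degrees of freedom and adding 3.76 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all 22215 probe sets, and an adjusted p under 0.05 was called. Errors marked ± are limma's moderated standard errors unless another is named. Gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over 24 lists, and list members were counted by their own adjusted p. With an estimated correlation in place of the preset none of the lists passed, the smallest adjusted p being 0.207. That form of camera rests on the 2 residual degrees of freedom, so it has little power with 4 arrays. The estimate was 0.11 for the G2 and M phase list but -0.0055, below the preset, for the S phase list. The unadjusted camera p of the latter still rose from 1.30e-12 to 0.0155. The loss of the calls therefore does not by itself show that correlation between genes accounts for the shifts. The self-contained test fry passed 21 of the 24 lists. It asks whether the genes of a list move on balance in one direction, not whether they differ from other genes.

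The design, the 24 lists, the alternatives and the rule for named genes were fixed before the data were examined, except where a choice is said to have been made afterwards. Named genes are TGFB1, the 12 genes with the largest increase and the 12 with the largest decrease among those past the threshold with both arrays of one group above both of the other, and up to 5 members of smallest p of each list. SMAD2, SMAD3, SMAD4, SMAD7, SKIL, CDKN2B, CDT1, E2F1, BUB3, BHLHE40, SNAI2, TGFBR3, EGFR, WNT5A, ZEB1, AXL, MITF, CD9, CD81, BST2, IRF7, VCAN, ITGA9, TPM1 and MMP1 lie outside a part of that rule or were singled out as exceptions after their values were seen. Some genes that the rule takes are not reported here. The replicate numbers 1 and 2 occur in both groups, and the labels do not say that a number marks a shared batch. Spiked controls were brighter in replicate 2 than in replicate 1 of both groups for 24 of 24 poly-A and 17 of 18 hybridization control probe sets, so a technical difference shared by number stays open. Alternatives were the second table, a second quantile normalisation, subtraction of array medians, a filter that kept probe sets above the 40th percentile of mean log2 value, an intensity trend with robust variances, the replicate number as a block, each array left out in turn, a minimum fold of 1.5, the mean of a gene's probe sets and other list tests. Scaling to the hybridization controls was added after the data were seen.

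The test was tested on simulated data with the probe sets' real means and the fitted variance, for the comparison of EWI-2 shRNA with control shRNA over 22215 probe sets. With 50 probe sets changed by each fold, it recovered 2% of 1.25-fold changes, 26% of 1.5-fold, 80% of 2-fold and 100% of 4-fold, with 5 false calls among 109. The Benjamini-Hochberg cut-off loosens as more probe sets change, and 7044 were called in the real data. The recovery rates therefore do not carry over to the real comparison and may understate it. A shift of 0.5 on the log2 scale given to the TGF-β response list was recovered as 0.49, and 1 other list passed, which shares 4 genes with it. The noise was drawn independently for each probe set and all other genes were left unchanged. This simulation therefore does not test the list calls under correlation between genes or among many changed genes. Precision is limited by the number of arrays: the median standard error of a log2 difference was 0.09 and the smallest called difference 0.24.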

Results

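The data describe gene expression in SK-mel-28, an established human melanoma cell line, after stable knockdown of EWI-2 (the product of the IGSF8 gene, an immunoglobulin superfamily protein that associates with tetraspanins). Total RNA was labelled with biotin and hybridised to 4 one-colour arrays, 2 from cells carrying a control shRNA and 2 from cells carrying an shRNA against EWI-2. The 4 arrays had closely matched distributions of RMA intensity, with medians of 62.2 and 61.9 in the control cells and 62.7 and 62.6 in the EWI-2 shRNA cells. Across 22215 probe sets the log2 values correlated at 0.998 within each group and at 0.982 to 0.983 between the groups. The standard deviation of the log2 difference was 0.17 between the control arrays, 0.15 between the EWI-2 shRNA arrays and 0.45 between the group means. The sources do not say whether the samples of a group came from separate cultures. The p-values of probe sets therefore rest on the spread between these samples, moderated across probe sets, which may be technical. Those of camera at the preset correlation compare the genes of a list with other genes and do not measure spread between samples. None of the gene names paired with the probe sets was IGSF8, so the EWI-2 transcript itself is not analysed here and the labels were not checked by the targeted gene.

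The single comparison of the design asks how loss of EWI-2 alters the transcriptome of melanoma cells, with the title naming TGF-β1, growth and metastasis. Genes of proliferation were lower in the EWI-2 shRNA cells, and genes of the TGF-β response, matrix, proteolysis and the invasive melanoma state were higher. These calls of the lists did not pass with an estimated correlation (camera, adjusted p = 0.207 for each list). That form of the test rests on 2 residual degrees of freedom. Of 12748 genes, 2180 were higher and 2356 lower at an adjusted p under 0.05 (limma, Benjamini-Hochberg over all probe sets), together 35.6% of the genes. Among these, 321 genes were at least 2-fold higher and 376 at least 2-fold lower, and 40 rose and 20 fell by more than 4-fold. At the level of probe sets, 3447 were higher and 3597 lower, 48.9% of the calls being upward. Scaling to the spiked hybridization controls, chosen after seeing the data, moved the median of all probe sets by -0.33 on the log2 scale. That is more than the controls' own median difference of 0.24. The scaling gave 1451 higher and 12629 lower, 10.3% upward, so directions are relative to the bulk of the genes. The poly-A controls, spiked before labelling, differed between the groups by a median of -0.076 and do not show such a shift. The count of calls was 4388 without EWI-2 shRNA replicate 1, 4569 without EWI-2 shRNA replicate 2 and 1066 against a minimum fold of 1.5. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333.

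The largest increase was in TCN1, which encodes a vitamin B12 binding protein. Its intensity rose from 99.2 to 1664, a log2 difference of 4.07 ± 0.08 (SE, 2 arrays per group, adjusted p = 0.000114). AKR1B10, an aldo-keto reductase, rose 10.5-fold from 23.7, and COL6A3, a chain of type VI collagen, rose 9.66-fold from 28.5 to 275. Several of the other leading genes are known from neural crest and glial cells. NGFR, the low-affinity nerve growth factor receptor, rose 9.65-fold (log2 difference 3.27 ± 0.14), the cadherin CDH19 rose 9.33-fold and the receptor phosphatase PTPRZ1 rose 8.36-fold. ENPP2, which encodes autotaxin, the secreted enzyme that makes lysophosphatidic acid, rose 8.14-fold to an intensity of 811, and both of its probe sets agreed. ITGA5, the α subunit of a fibronectin receptor, rose 7.12-fold. The remaining leading increases were in the glutamate receptor subunit GRIK2 at 6.95-fold, the coagulation inhibitor TFPI at 6.68-fold, PMEPA1, an inducible inhibitor of TGF-β signalling, at 6.66-fold and the histone gene H2BC21 (HIST2H2BE in the file) at 6.12-fold. For TFPI the 5 probe sets ranged from 0.16 to 2.74.

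The largest decrease was in LANCL1, a glutathione-binding protein gene, which fell from 1529 to 158, a log2 difference of -3.28 ± 0.11 (SE, adjusted p = 0.000147). Its other probe set fell less, by 2.70-fold from 345 to 128. DOCK9, an exchange factor for CDC42, fell 6.57-fold, PRPS2, an enzyme of nucleotide precursor synthesis, fell 6.06-fold, and RRP1B, a nucleolar protein gene, fell 5.86-fold. SLC35A5 was lower by 5.72-fold, the galactosyltransferase B4GALT1 by 5.61-fold, the ion channel TRPA1 by 5.43-fold and the sphingosine phosphate phosphatase SGPP1 by 4.97-fold. The immediate early transcription factor EGR3 was lower by 4.91-fold, the replication factor CDC45 by 4.83-fold and the transporter SLC47A1 by 4.60-fold. CEACAM1, a cell adhesion molecule, fell from 2587 to 575, and each of its 5 probe sets passed in the same direction. Another probe set of DOCK9, RRP1B and B4GALT1 showed a log2 difference of 0.07, 0.11 and 0.10, so these falls rest on part of each gene's probe sets. Both arrays of one group lay above both of the other for each of these 24 genes, as the rule for naming them asks. Such a separation was seen for 67.1% of all genes, and chance gives 33.3%.

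**Figure D1:**
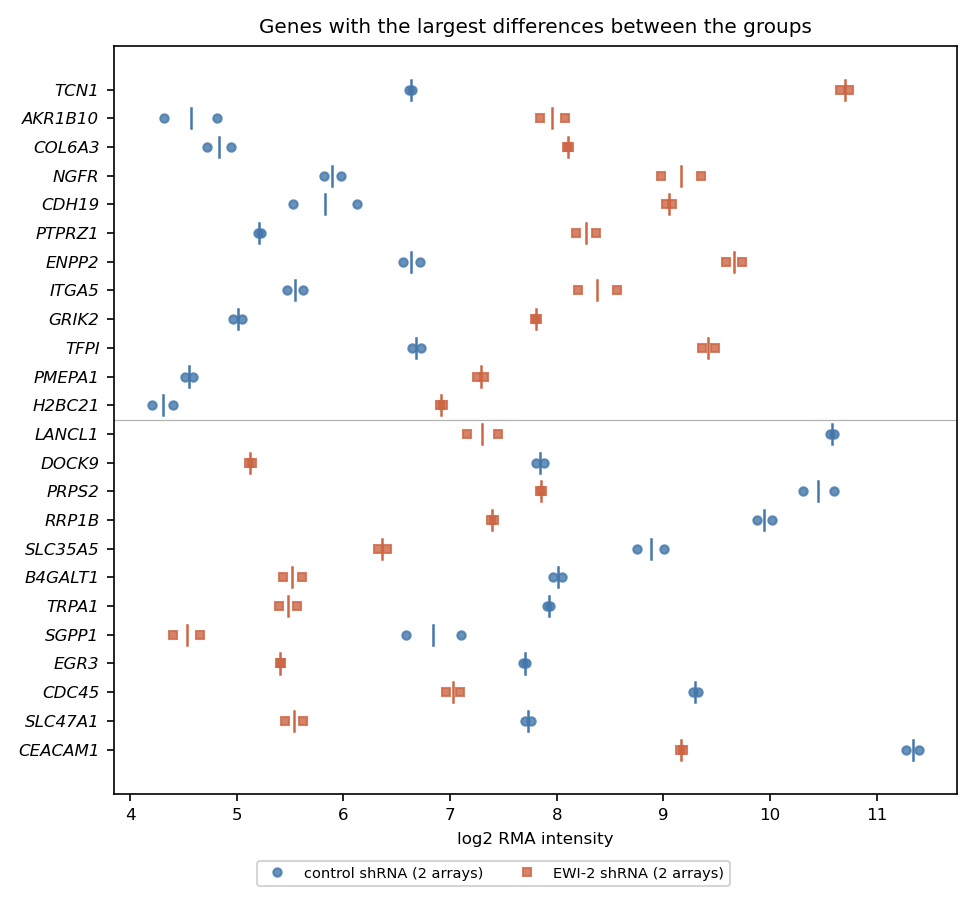
Log2 RMA intensity (x axis) of the 12 genes with the largest increase (above the grey line) and the 12 with the largest decrease, with a circle per control shRNA array, a square per EWI-2 shRNA array and a vertical bar at each group's mean. TCN1 rose from 99.2 to 1664 and LANCL1 fell from 1529 to 158 on the linear scale, and the arrays of a group lie closer to each other than to the other group in every row.

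The title of the series names TGF-β1. The transcript of TGFB1 rose 2.01-fold, from an intensity of 33.5 to 67.3 (log2 difference 1.01 ± 0.12, adjusted p = 0.00202). That value is from the brighter of its probe sets, and the other, at 15.1 and 15.5, lay at the level of the Trpn control probe sets (13.4 to 15.5) and differed by 0.03 ± 0.08. The increase did not pass a test against a minimum fold of 1.5 (adjusted p = 0.111). Of 28 measured components of the TGF-β pathway, 12 rose, 2 fell and 14 did not pass, with the same counts when adjusted over the list alone. TGFBR2, the type II receptor, rose 3.45-fold from 486 to 1676, the inhibitory SMAD6 rose 3.43-fold, and the latent TGF-β binding proteins LTBP2 and LTBP1 rose 2.15-fold and 1.86-fold. The other probe sets of SMAD6, at intensities of 16.3 to 20.8, had log2 differences from -0.09 to 0.17 and did not pass. The fallen members were SMAD1, a mediator of BMP signalling, at 1.87-fold and the co-receptor TGFBR3 at 1.39-fold. SMAD2, SMAD3 and SMAD4, the receptor-activated and common mediators, had log2 differences of -0.02, 0.02 and -0.15 and did not pass. The list shifted upward as a whole (camera, adjusted p = 0.00654), and the adjusted p was 0.207 with an estimated correlation.

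Of 30 genes known to respond to TGF-β, 15 rose, 2 fell and 13 did not pass, and 18 rose and 3 fell when adjusted over the list alone. PMEPA1 rose most. The secreted adhesion protein TGFBI rose 4.67-fold from 33.8 to 158 (log2 difference 2.22 ± 0.11), and the matricellular genes CCN2 (CTGF in the file) and CCN1 (CYR61 in the file) rose 2.82-fold and 2.65-fold. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose 1.87-fold. The fallen members were BHLHE40 (1.37-fold) and SNAI2 (1.24-fold). SMAD7 and SKIL, feedback inhibitors of the pathway, had log2 differences of 0.17 ± 0.08 and -0.05 ± 0.10, and CDKN2B had -0.04 ± 0.07, none of which passed. The mean log2 difference of the list was 0.58 ± 0.83 (SD over genes), upward by camera (adjusted p = 0.000585), and the adjusted p was 0.207 with an estimated correlation.

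Genes of cell division fell together. Of 29 genes of the G2 and M phases, 28 fell and none rose, and the mean log2 difference was -1.02 ± 0.34 (SD over genes). BIRC5, which encodes survivin, fell 3.52-fold from 1627 to 462, the anaphase activator CDC20 fell 2.71-fold, the spindle genes DLGAP5 and KIF20A fell 2.40-fold and 2.29-fold, and the checkpoint kinase BUB1B fell 2.21-fold. BUB3 was the member that did not pass, at -0.31 ± 0.10, although another of its probe sets fell by 0.70. Of 26 genes of DNA replication and S phase, 24 fell and none rose, with a mean of -0.85 ± 0.48. CDC45 was followed by the DNA polymerase subunit POLE2, which fell 3.57-fold, the flap endonuclease FEN1 at 2.26-fold, POLA1 at 2.15-fold and the thymidylate synthase TYMS at 2.08-fold. CDT1 and E2F1 did not pass, at -0.53 ± 0.21 and 0.22 ± 0.10. Adjusted over the list alone, 29 of the former and 25 of the latter fell. Both lists were lower by camera, with adjusted p = 5.67e-15 and 1.56e-11, and for both the adjusted p was 0.207 with an estimated correlation.

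Genes of the invasive or undifferentiated melanoma state were higher. Of 24 measured, 14 rose, none fell and 10 did not pass, and adjusted over the list alone the counts were the same. The mean log2 difference was 0.88 ± 1.00 (SD over genes). NGFR led, and the urokinase receptor PLAUR rose 5.35-fold, the AP-1 transcription factor JUN 4.32-fold and CCN2 2.82-fold. The receptor kinase AXL rose 2.71-fold and N-cadherin, CDH2, rose 2.19-fold, and another probe set of AXL stood at 0.08. EGFR, WNT5A and ZEB1 had log2 differences of -0.15, -0.07 and 0.02 and did not pass. The list was higher by camera (adjusted p = 5.83e-05), and the adjusted p was 0.207 with an estimated correlation. The list shares 4 genes with the TGF-β response list, among them CCN1, CCN2 and TPM1, so their counts are not independent.

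Melanocyte differentiation genes moved both ways, with 4 of 23 higher, 8 lower and 11 not passing, and 6 higher and 8 lower when adjusted over the list alone. Tyrosinase, TYR, the first enzyme of melanin synthesis, rose 3.45-fold from 2298 to 7929. The melanosome transport genes RAB38 and RAB27A fell 2.57-fold and 2.18-fold, P-cadherin, CDH3, fell 2.10-fold, and the melanosomal transporter OCA2 fell 1.62-fold. For RAB27A the 4 probe sets ranged from -1.14 to -0.37 on the log2 scale. MITF, the master transcription factor of the lineage, was at 6843 and 6426 and did not pass (log2 difference -0.09 ± 0.08, adjusted p = 0.438). The list as a whole did not pass (camera, adjusted p = 0.688), with a mean of -0.09 and a median of 0.04. Mesenchymal genes had 5 members higher, 2 lower and 10 not passing, and 5 and 3 when adjusted over the list alone (camera, adjusted p = 0.27, and 0.0400 with scaling to the hybridization controls), and the leading ones were ITGA5, MMP2, SPARC and CDH2. Epithelial genes had 2 higher, 5 lower and 10 not passing, also when adjusted over the list alone (camera, adjusted p = 0.688). E-cadherin, CDH1, fell 2.86-fold from 167 to 58.3, desmoplakin, DSP, fell 2.06-fold and the splicing regulator ESRP1 fell 1.92-fold, while the junction protein TJP1 rose 1.80-fold.

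Genes of the cell surface and its matrix were mostly higher. Of 29 extracellular matrix genes, 17 rose and 1 (VCAN) fell. COL6A3 led, perlecan, HSPG2, rose 3.44-fold, the laminin chains LAMA4 and LAMC1 rose 2.87-fold and 2.59-fold, and SPARC rose 2.19-fold from an already high 4087. For LAMA4 the 5 probe sets ranged from 0.10 to 1.52 on the log2 scale. One of them, at 193 and 240 in control and EWI-2 shRNA cells, rose by 0.31. The other probe set of LAMC1, at 744 and 892, rose by 0.26, so the size of these increases depends on the probe set. Of 26 matrix proteases and inhibitors, 17 rose and 1 fell. ADAMTS1, MMP8 and the gelatinase MMP2 rose 3.12-fold, 2.83-fold and 3.52-fold, and the fallen member was the collagenase MMP1, which fell 2.44-fold from 359 to 147. Of 18 integrin genes, 10 rose and 1 (ITGA9) fell. ITGA5 was followed by ITGA2 at 2.43-fold, ITGB3 at 1.88-fold and ITGB1 at 1.75-fold. Adjusted over the list alone, 17 matrix genes, 17 protease genes and 10 integrin genes rose and 1, 1 and 2 fell. The adjusted p by camera was 4.53e-05 for matrix genes, 5.50e-06 for proteases and 0.00204 for integrins, and with an estimated correlation the adjusted p was 0.207, 0.207 and 0.372.

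EWI-2 acts in the membrane with tetraspanins. Of 17 measured genes of the EWI family and tetraspanins, 7 rose, 1 fell and 9 did not pass, also when adjusted over the list alone. CD151, a tetraspanin that binds laminin-binding integrins, rose 2.05-fold from 629 to 1288, and TSPAN7, CD53 and TSPAN13 rose 1.90-fold, 1.88-fold and 1.42-fold. IGSF3, a member of the EWI family, fell 1.51-fold (adjusted p = 0.00673, and 0.05003 without EWI-2 shRNA replicate 1). CD9 and CD81, the main tetraspanin partners of EWI-2, had log2 differences of -0.08 ± 0.08 and 0.17 ± 0.08 and did not pass. The shift of the list passed narrowly (camera, adjusted p = 0.0431) and the adjusted p was 0.309 with an estimated correlation. It was 0.0541 without control shRNA replicate 2 and 0.0779 without dim probe sets, and scaling to the hybridization controls, which lowers every log2 difference alike, took the mean of the list from 0.28 to -0.051 and left the camera call (adjusted p = 0.0236).

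Interferon-stimulated genes were lower, with 17 of 28 fallen, 2 risen and 9 not passing, and 18 fallen and 2 risen when adjusted over the list alone. IFIT1 fell 3.05-fold from 167 to 54.6, HERC6 fell 2.66-fold, HERC5, a ligase for ISG15, fell 2.49-fold, and USP18 fell 2.25-fold, while BST2 and IRF7 rose 1.57-fold and 1.46-fold. The mean of the list was -0.58 ± 0.58 (SD over genes, camera adjusted p = 2.68e-06), and the adjusted p was 0.207 with an estimated correlation. This list had been included as a check of responses to vectors. No other construct was compared, so a differing response of the lines to their vectors cannot be told apart from an effect of EWI-2. Of 22 cholesterol synthesis genes, 12 fell and 2 rose, also when adjusted over the list alone. MSMO1 (SC4MOL in the file) and EBP fell 2.44-fold and 2.30-fold, and INSIG1, which retains the sterol regulator SREBP in the endoplasmic reticulum, rose 2.53-fold. The adjusted p of the list was 0.00277, and 0.207 with an estimated correlation.

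In the other lists no shift passed. Of 18 measured p53 targets, 9 fell and 3 rose, and 10 fell and 4 rose when adjusted over the list alone (camera, adjusted p = 0.0819, 0.0494 without EWI-2 shRNA replicate 1, 0.0323 with the mean of a gene's probe sets, and up to 0.432 over the other settings of camera). SESN1, DDB2 and BAX fell 2.35-fold, 1.87-fold and 1.86-fold and CDKN1A rose. Inflammatory and NF-κB genes split evenly at 5 and 5 of 24, also when adjusted over the list alone (adjusted p = 0.756, camera downward, mean 0.07, median -0.07), with IL24 up 5.21-fold, CXCL8 (IL8 in the file) up 3.05-fold and SOD2 down 2.05-fold by its brightest probe set (another, at 46.5 and 43.1, differed by -0.11). Antigen presentation genes had 9 higher and 7 lower of 23, also when adjusted over the list alone (adjusted p = 0.989, camera upward, mean -0.04, median 0.03). The immunoproteasome subunit PSMB9 fell 2.24-fold and HLA-DRA fell 2.10-fold. Hypoxia and glycolysis genes had 7 higher and 11 lower of 28, and 9 and 12 when adjusted over the list alone (adjusted p = 0.688), with the glucose transporter SLC2A3 up 3.79-fold (another of its probe sets at 0.05) and BNIP3 down 2.90-fold. Unfolded protein and ATF4 response genes had 10 higher and 7 lower of 23, also when adjusted over the list alone (adjusted p = 0.345). The chaperone DNAJB9 rose 2.83-fold and TRIB3 fell 2.01-fold. Of 30 ribosomal protein genes 2 fell and none rose, and 1 fell when adjusted over the list alone (adjusted p = 0.688), and the mean was -0.03 ± 0.15. Of these, RPS4X fell by 0.45, and RPS3, at -0.30, did not pass when any 1 of the 4 arrays was left out or with the replicate block (adjusted p = 0.0511).

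Markers of other cell types were included as lists. None of the 11 endothelial markers passed, 2 of 13 fibroblast markers rose (COL6A3 and LUM), 2 of 14 keratinocyte markers rose (LAMB3 and KRT17), and among 17 leukocyte markers LAPTM5, CD53 and CD3D rose and CORO1A fell. The camera adjusted p of these lists was 0.819, 0.819, 0.506 and 0.688. The fibroblast markers had a mean of 0.24 and a median of -0.01. Adjusted over the list alone, the counts were the same except that 1 keratinocyte marker rose. LAPTM5, a lysosomal membrane protein gene, rose 4.21-fold to 168. The changes of KRT17, CD3D and CORO1A, at 0.27, 0.27 and -0.27, did not pass when any 1 of the 4 arrays was left out, and among those 4 settings the change of LUM, at 0.50, passed only without control shRNA replicate 2. It was 0.34, 0.47 and 0.53 without control shRNA replicate 1, EWI-2 shRNA replicate 1 and EWI-2 shRNA replicate 2. With the replicate number as a block, LUM, KRT17, CD3D and CORO1A did not pass either, at adjusted p = 0.0516, 0.0630, 0.0612 and 0.0567.

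**Figure D2:**
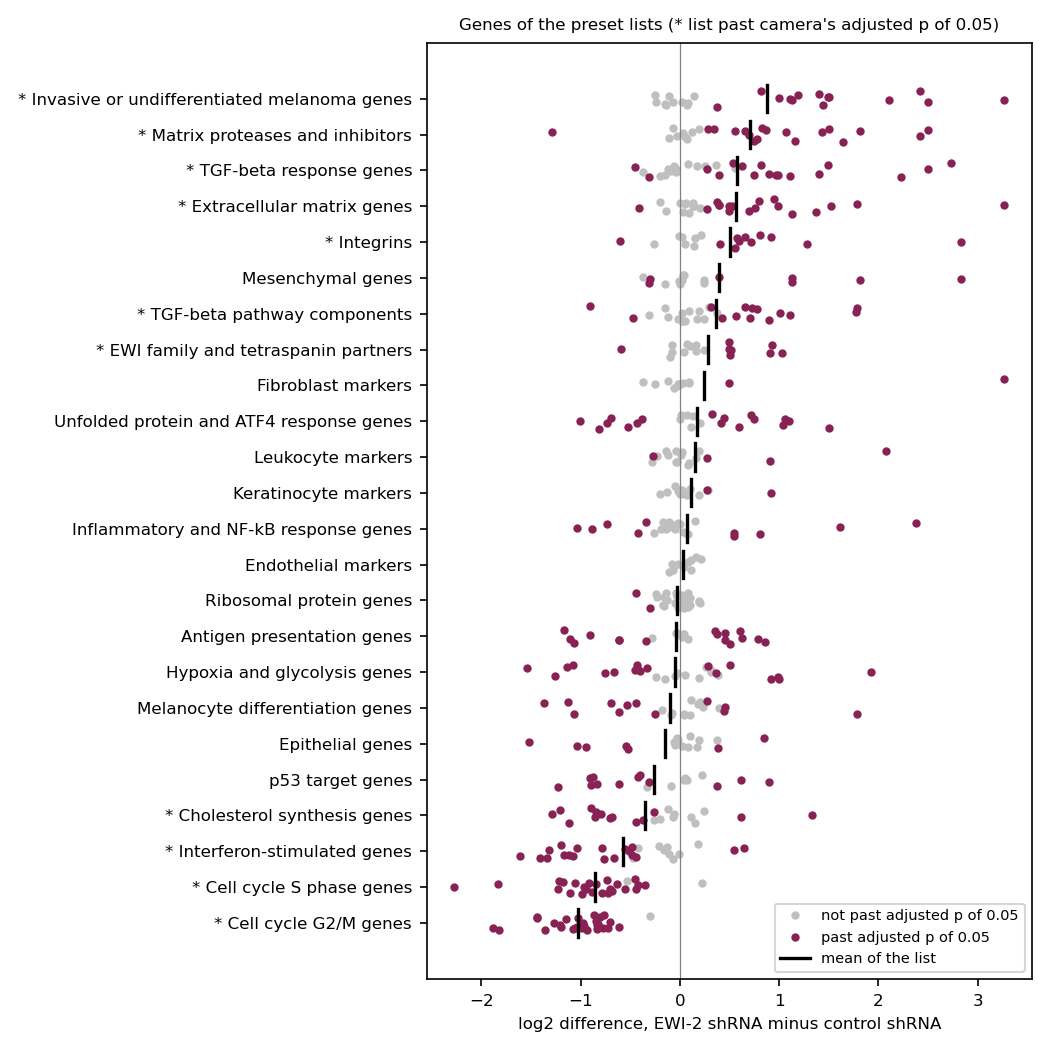
Log2 difference, EWI-2 shRNA minus control shRNA (x axis), of each measured gene (points) in the 24 lists, sorted by the mean of the list (black bar), with purple points past an adjusted p of 0.05 and stars on the 11 lists past camera's threshold, of which none passed with an estimated correlation (smallest adjusted p = 0.207). The G2 and M phase list, with a mean of -1.02, has every point below 0, and the invasive melanoma list, with a mean of 0.88, has no purple point below 0.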

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

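All tests in this part were chosen after the result was seen. The spiked hybridization controls, bacterial and phage sequences that take no part in the comparison of genes, were brighter on the EWI-2 shRNA arrays by a median log2 difference of 0.24 over 18 probe sets, from 0.07 to 0.39, and both EWI-2 shRNA arrays lay above both control arrays for 16 of them. The 24 poly-A control probe sets, spiked before labelling, differed between the groups by a median of -0.076. Each of them was brighter in replicate 2 than in replicate 1 in both groups, by a median of 0.40, and so were 17 of the 18 hybridization controls, by a median of 0.11.

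The pattern weighed here is the 7044 probe sets called between the groups. A hybridization or scan difference would move them by about as much as the controls. Of them, 76.8% moved by more than 0.39, the largest difference of any of the 42 spiked control probe sets, with 2574 higher and 2834 lower. For these, that argues against a difference between the groups of the controls' size. They were called for their large differences, however, and poly-A controls differed by a median of 0.40 between replicates, so 0.39 does not bound every technical difference. The other 23.2% moved by no more than 0.39. Those called higher lie within the controls' range and cannot be told apart from such a difference. Those called lower, by at least 0.240, lie below every spiked control, the lowest being a poly-A control at -0.237. All 18 hybridization controls rose, by 0.07 to 0.39, while the poly-A controls on the same arrays differed by a median of -0.076. Values are relative to the bulk of the genes after quantile normalisation. The rise of the hybridization controls therefore does not tell whether a hybridization difference moved the probe sets called lower. Unequal RNA degradation is argued against by the 3' to 5' ratios of the ACTB and GAPDH control probe sets, which differed between the groups by at most 0.089 on the log2 scale, under the smallest called difference of 0.24. Differences between the 2 stable lines that do not depend on EWI-2, such as an effect of the shRNA on other transcripts, stay open beside an effect of EWI-2 itself: 51.9% of the called genes were lower, and with 1 construct per group there was no second construct or rescue to compare.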

How the results depend on the processing

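The scaling to hybridization controls was chosen after the data were seen. Against 7044 called probe sets (3447 higher, 3597 lower), that scaling gave 14080 (1451 and 12629), which follows from its shift of the median by -0.33, and a minimum fold of 1.5 gave 1066 (497 and 569). Leaving out 1 array gave 4388 to 5278 (2134 to 2492 higher, 2254 to 2786 lower) with 1 residual degree of freedom, the lone array being assumed to vary like the other group. The count was 4388 without EWI-2 replicate 1 and 4569 without EWI-2 replicate 2. Of these calls 4292 and 4454 were also called with all arrays. The replicate block gave 6361 calls, and 6173 of them were shared with the fit without it. The correlation of same-numbered deviations was 0.08. The block ended the calls of RPS3, LUM, KRT17, CORO1A and CD3D among the named genes and changed no list call. The number of lists past the threshold, 11, became 0 with an estimated correlation (TGF-β response 0.58, S phase -0.85 and G2 and M phase -1.02, all with adjusted p = 0.207) and 21 with fry, and was 10 to 12 under the other settings. Scaling to the hybridization controls turned the mean of the EWI and tetraspanin list to -0.051, KRT17 to -0.062 and CD3D to -0.063, by the same shift. That shift comes from the median control value of each array and exceeds the controls' median difference of 0.24, which is smaller than these 3 values (0.28, 0.27 and 0.27) before scaling. TGFB1 ranged from 0.52, as the mean of its probe sets, to 1.16. FN1 was not called against the minimum fold, at 0.06 with the hybridization controls, 0.34 without control replicate 1, 0.40 without EWI-2 replicate 1 and 0.39 without EWI-2 replicate 2. Over all named genes and settings, 1594 values kept their direction and side of the threshold, 70 were no longer called, 25 became called and 2 reversed. Of the 1594, 131 came from the second table, which held the same values. Apart from TGFB1, these genes were picked by size of change or p on the same arrays, so this stability is partly built in. No value is given for the IGSF8 transcript under any setting, since no probe set was paired with that name. Signal over background limits the dim genes: both groups lay at or below the highest Trpn control value, 15.5, for 2865 probe sets, of which 17 were called.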

Other observations

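All lists in this part were drawn up after the main results had been seen, and genes already in a preset list or among the 24 largest changes were left out of them. The tests of cell type markers and the restriction to genes with 2 called probe sets were chosen after the result was seen. Genes of homologous recombination repair fell with the replication genes: 15 of 19 fell and none rose, with a mean log2 difference of -0.66 ± 0.36 (SD over genes). BRCA1 and MRE11 had log2 differences of -0.98 and -1.16. Ribosome biogenesis genes were lower too, with 11 of 18 fallen and none risen, led by BOP1 at -1.11 (another probe set at 0.03) and DKC1, the pseudouridine synthase dyskerin, at -1.08. By camera, adjusted over 6 lists, the adjusted p was 2.26e-07 and 0.000155, and for both the adjusted p was 0.133 with an estimated correlation. Adjusted over the list alone, 16 and 12 fell and none rose.

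Lysosomal genes were higher. Of 19 measured, 15 rose and none fell, among them the protective protein CTSA at 0.96, the sialidase NEU1 at 0.84, the peptidase TPP1 at 0.84 and the calcium channel MCOLN1 at 0.79, while LAMP1 and LAMP2 stood at -0.02 and -0.03 and did not pass. Of 11 histone genes 5 rose and none fell, with H2AC6 at 1.51 and H2BC5 at 1.38, in the same cells in which S phase genes fell. Of 18 neural crest and Schwann lineage genes, apart from NGFR, CDH19 and PTPRZ1, 8 rose and none fell, including SLC22A17 at 0.98, SEMA3B at 0.91 and S100B at 0.76, with another probe set of SLC22A17 at 0.14 and of SEMA3B at 0.03. The adjusted p was 9.56e-06, 0.0163 and 0.0108 for these lists, and with an estimated correlation the adjusted p was 0.133, 0.181 and 0.151. Adjusted over the list alone, 16 lysosomal genes rose and 1 (SGSH, at -0.31) fell, 5 histone genes rose, and 8 neural crest and Schwann lineage genes rose and 1 (AQP1, at -0.32) fell. AP-1 family genes moved both ways, with JUND at 1.23 and MAF at 0.73 (lowest of its probe sets -0.22) risen and FOS at -0.92 and MAFF at -0.58 fallen, and 3 rose and 2 fell when adjusted over the list alone (adjusted p = 0.921).

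Some markers of other cell types rose: LAPTM5 and CD53, known as leukocyte genes, by 2.07 and 0.91 on the log2 scale, and COL6A3, among the fibroblast markers, by 3.27. Leukocyte RNA in the EWI-2 shRNA samples would raise the other markers by a similar amount, and the median of the other 15 was -0.033 with an SD of 0.17 and a highest value of 0.27, which argues against it, and PTPRC was at 15.2 and 14.9 in control and EWI-2 shRNA cells. By the brightest probe set of each gene, the other 12 fibroblast markers had a median of -0.018, an SD of 0.21 and a highest value of 0.50, which argues against fibroblast RNA as the source of a rise of 3.27, and COL1A2 stood at 19.3 and 19.1. A dimmer probe set of COL1A1 rose from 13.9, within the range of the Trpn controls, to 30.9 (adjusted p = 0.00641), against -0.37 for the brightest one, and 1 of 4 DCN probe sets rose by 0.25. Expression by the melanoma cells themselves stays open and was not tested.

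Some genes gave called probe sets in opposite directions, 61 of the 1296 genes with at least 2 called probe sets. In ARMC8 the log2 differences were -1.70 ± 0.08 and 1.01 ± 0.08, in TMF1 -1.81 ± 0.10 and 0.86 ± 0.12, and in IGF1R, the receptor of insulin-like growth factor, -0.35 ± 0.07 and 1.31 ± 0.07. Cross-hybridizing probe sets, marked by an x in their name, were called in 19.7% of these genes and in 24.9% of the 1235 others (odds ratio 0.74, 95% interval 0.35 to 1.44, Fisher's exact test, two-sided p = 0.447), which leaves that explanation undecided. Among genes with exactly 2 called probe sets, the dimmer one was lower by 0.71 on the log2 scale in the 39 opposed genes than in the 919 others (two-sided permutation test, p = 0.04), but its median of 6.83 lay above the 5.96 of all probe sets, so a role of signal near background stays open. A change in transcript ends or splicing may also give this pattern and was not tested.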
